A study of Drosophila melanogaster with 12 samples.

How the data were processed

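RNA was measured by polyA-selected sequencing of whole heads of adult Oregon-R fruit flies (Drosophila melanogaster), 200 heads per sample, in 12 libraries. The 4 groups of 3 libraries were females and males kept in same-sex groups of 25 and females and males kept alone, each for 7 days, after 3 to 5 days of housing with both sexes. Per the labels, replicate 0 of each group was sequenced in batch 1 and replicates 1 and 2 in batch 2. The labels do not say whether the pools of heads came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

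The deposited table holds whole-number read counts per feature, not normalised, for 24228 features, of which 17856 carry a gene identifier; the others are mostly transposable element insertions. The submitters' processing notes name STAR 2.7.10b, Picard 2.27.5, HTSeq 2.0.5, R 4.4.0 and edgeR 4.4.1 without giving their roles. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Between 10.2% and 13.2% of each column's total stood in lines of the count output that name no gene (reads without a feature, ambiguous reads and reads aligned to several places), and these were left out of library sizes and tests. A further number per gene in the deposited table, not tied to a sample, was not used. Because strand use is not known, reads of overlapping genes on opposite strands cannot be told apart. Among the genes named below this concerns also Boh1, CG7227, Sas10, CG11180, Dsk, Tep2, Gnmt, Hsp83, PGRP-SD, AttC, CG34324, S-Lap2, sxe2, roX1, apolpp, LpR2 and tim, which are uncertain for that reason. Clk overlaps a gene on the same strand, and Amy-p and Amy-d, which are near-identical copies, are uncertain as single genes.

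Total counts over features ran from 2584050 to 17122099 per library. Group-housed females had 5351208 to 17122099, isolated females 2584050 to 9637727, group-housed males 6291972 to 14319293 and isolated males 5312973 to 14535524. The deposited column of isolated male replicate 1, which had the 14535524 counts, is marked as merged; what was merged is not given in the sources used here, and it was used as 1 replicate. The other male libraries of batch 2 had 5312973 to 7743936 counts. Pairs of replicates differed far beyond sampling noise (chi-square per degree of freedom 4.48 to 65.7 over genes with at least 10 reads in the pair), so each library was counted as 1 replicate.

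Counts were analysed with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Features were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 10238. Scaling factors were computed by TMM, and 1 quasi-likelihood model with 4 group means and the batch was fitted to all 12 libraries with robust estimation, leaving 7 residual degrees of freedom. Each contrast was tested with glmQLFTest and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p below comes from this test unless another is named. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels of single genes are CPM, counts relative to TMM-scaled library sizes as edgeR gives them, with SD over 3 libraries. Levels of whole gene lists are sums of CPM relative to the total counts over features, without TMM scaling. For takeout, a two-sided exact permutation test of log2 CPM within each sex was added, which cannot give a p below 0.1 with 3 libraries against 3.

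Gene lists for 35 functions and cell types were written before the data were examined, as were the groups, the tests, most of the alternatives and the rule for naming genes; 9 of 596 listed symbols were not matched in the table. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists tested in a contrast, with the estimated correlation beside it. The naming rule took takeout, then per contrast the 10 largest fold changes in each direction among genes passing the threshold with a mean log2 CPM of at least 1 (5 for the comparisons of the sexes), the 3 smallest p where none passed at that level, and up to 4 members of each list with the smallest p (for the comparisons of the sexes, of the sex-biased list alone). Other genes named below were chosen after their values were seen: the rest of the lower genes in males, and members of a list named to show its spread.

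Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, other batch terms, subsets of libraries, a minimum fold of 1.2, and leaving out each library in turn. On simulated counts with the means, dispersions and library sizes of these libraries and 200 changed genes, the female contrast recovered 65% of genes changed 2-fold and 81% of genes changed 4-fold among 10154 genes tested. The male contrast recovered 68% and 87% among 10166 genes tested. False calls made up 4.58% and 5.49% of calls. The difference between the sexes recovered fewer: 45% of 2-fold and 68% of 4-fold changes simulated in females, with 6.61% false calls, and 32% and 77% of those simulated in males, with 5.22% false calls. With no change simulated none of the 3 contrasts called a gene. The simulated genes were drawn independently, with 1 dispersion per gene for all groups. The real libraries need not behave so, and these shares may not carry over to them. Gene identifiers were looked up in the BDGP6.54 annotation, where 24186 of the 24228 features matched.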

Results

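The series asked how a week alone changes gene expression in the fly head and whether females and males respond alike, with takeout as the named gene. Each of the 12 libraries held RNA from 200 heads, and the 4 groups (isolated or group-housed, female or male) had 3 libraries each. Isolated females of batch 2 were the shallowest libraries, at 2584050 and 3224485 counts.

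takeout (symbol to, FBgn0039298), a secreted protein of the juvenile hormone binding protein family linked to feeding and the clock, was higher in isolated than in group-housed females. In the BDGP6.54 annotation it is a protein-coding gene on chromosome arm 3R, from 25240180 to 25241668 on the plus strand. Its level was 105 ± 51.8 CPM (SD, n = 3) in group-housed females and 717 ± 155 CPM (SD, n = 3) in isolated females. The log2 fold change was 2.80 (SE 0.34, edgeR adjusted p = 0.000387), and each isolated library exceeded each group-housed one in 9 of 9 pairs. In males it stood at 600 ± 178 CPM (SD, n = 3) in groups and 496 ± 75.0 CPM (SD, n = 3) alone, a log2 fold change of -0.28 (SE 0.32, edgeR adjusted p = 1). The female response exceeded the male response by 3.08 on the log2 scale (SE 0.46, edgeR adjusted p = 0.00679). The exact permutation test gave p = 0.1 in females, the smallest it can give, and p = 0.4 in males. Within batches the female log2 difference was 1.92 in batch 1, from 1 library per group, and 3.36 in batch 2, and the male one was -0.17 and -0.28. Without group-housed female replicate 2 the difference between the sexes was 3.11 with adjusted p = 0.082, and with isolated females represented by replicate 0 alone it was 2.56 with adjusted p = 0.139.

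**Figure D1:**
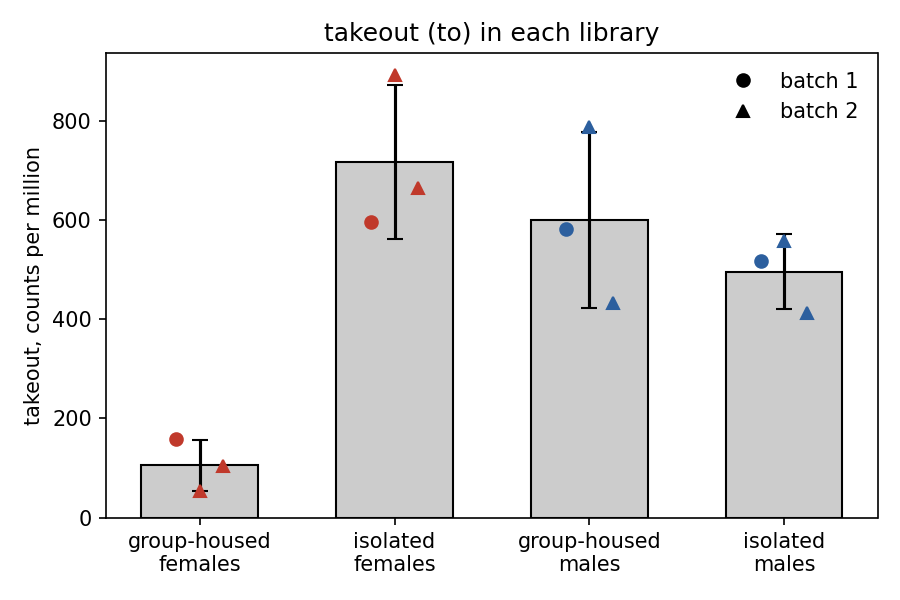
takeout level in CPM (vertical axis) in the 4 groups; bars are means, error bars SD over 3 libraries, and points are libraries, with circles for batch 1 and triangles for batch 2. Group-housed females average 105 CPM, and the other groups average 496 to 717 CPM.

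Many genes differed between isolated and group-housed females, most of them higher under isolation. Fbp1, which encodes a fat body receptor for larval serum proteins, rose from 16.3 ± 12 to 602 ± 89 CPM (SD, n = 3), a log2 fold change of 5.30 (SE 0.35, adjusted p = 1.75e-06). The storage proteins Lsp1alpha and Lsp2 rose from 74.0 ± 19.6 to 1609 ± 366 CPM and from 480 ± 339 to 4638 ± 273 CPM (SD, n = 3), log2 fold changes of 4.45 (SE 0.18) and 3.44 (SE 0.30). atk rose by 4.56 (SE 0.19), the gustatory receptor gene Gr59f by 3.96 (SE 0.29), the odorant binding protein gene Obp99b by 3.63 (SE 0.36), and the takeout family member CG11854 by 3.81 (SE 0.61). meep, fiz and CG34166 rose by 4.06, 3.43 and 3.25. Of these, atk, meep, CG11854, Lsp2 and fiz overlap a gene on the other strand in BDGP6.54. In all, 334 genes were higher and 22 lower in isolated females among 10238 tested, so that 93.8% of calls were higher; with library totals alone 79.8% were. Taken separately in each batch, the changes of all tested genes correlated by r = 0.4 across genes, and 61.5% had the same sign. On the first principal component of log2 CPM (29.1% of the variance), isolated female replicates 1 and 2 stood apart at 60.1 and 46.1, against 3.48 for replicate 0 and at most 22.0 for the other libraries. They also had the lowest totals and scaling factors (0.86 and 0.893). With isolated females represented by replicate 0 alone, assumed to vary like the other groups, 91 genes passed, 90 of them higher, and 31 of 56 named genes other than takeout lost their call without a change of sign; this setting was added after seeing the data. The total of 356 was 158 without group-housed female replicate 0, 191 without isolated female replicate 0, 209 without isolated female replicate 1 and 229 without isolated female replicate 2.

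Of the 22 genes that fell in isolated females, 20 had a mean log2 CPM of at least 1. CNMa, which encodes a neuropeptide, fell by 2.02 on the log2 scale (SE 0.53, adjusted p = 0.0435), from 6.39 ± 0.193 to 1.46 ± 0.881 CPM (SD, n = 3). Boh1 fell by 1.98 (SE 0.50), CG7227 by 1.32 (SE 0.33) and Sas10 by 1.15 (SE 0.30). CG44242, CG11180, GIIIspla2, VhaM9.7-a and CG11211 fell by 1.14, 1.11, 0.99, 0.93 and 0.89. MsrA, a methionine sulfoxide reductase, fell by 0.90 (SE 0.15, adjusted p = 0.00139). Dsk, which encodes the satiety peptides drosulfakinins, fell by 0.84 (SE 0.17, adjusted p = 0.0102). Of 12 fits with 1 library left out, CNMa lost its call in 10, Boh1 in 9, CG7227 in 6, Sas10 in 10, CG44242 in 4, CG11180 in 11, GIIIspla2 in 8, VhaM9.7-a in 3, CG11211 in 2 and Dsk in 3. The adjusted p reached 0.186 (CNMa), 0.199 (Boh1), 0.288 (CG11180) and 0.141 (CG11211) without group-housed female replicate 0, 0.193 (CG7227), 0.273 (GIIIspla2) and 0.0568 (Dsk) without isolated female replicate 0, 0.119 (VhaM9.7-a) without isolated female replicate 1, and 0.2 (Sas10) and 0.149 (CG44242) without isolated female replicate 2.

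Among the gene lists, that of fat body genes passed upward in females, with members that differed in size. Of 17 tested, 6 were higher and none lower (13 higher when adjusted over the list alone), with a median log2 fold change of 0.87 (camera adjusted p = 1.48e-28; adjusted p = 0.000298 with an estimated correlation). Beside Fbp1 and the storage proteins, the yolk protein genes Yp2 and Yp3 rose by 1.70 (SE 0.39) and 1.43 (SE 0.33), and the lipid carrier gene Apoltp by 0.93 (SE 0.20); the Apoltp call was lost in 3 of 12 fits with 1 library left out (adjusted p = 0.118 without group-housed female replicate 0). The lipophorin receptor genes LpR1 and LpR2 stood at 0.03 (SE 0.14, adjusted p = 0.956) and 0.06 (SE 0.13, adjusted p = 0.879). Without TMM scaling, the fat body list took 31623 ± 4149 CPM in group-housed and 61397 ± 7161 CPM in isolated females (SD, n = 3). In group-housed and isolated males it took 15156 ± 1796 and 15318 ± 1778 CPM (SD, n = 3). A list of sex determination and sex-biased head genes had 6 of 18 members higher (9 adjusted over the list alone; camera adjusted p = 4.07e-09, adjusted p = 0.00796 with an estimated correlation). The 6 were takeout, Obp99b, Obp99a, Yp2, Yp3 and fit, a female-enriched gene that rose by 2.29 (SE 0.29). In BDGP6.54 fit overlaps asRNA:CR45046 on the same strand and CG31465 on the other strand, and is uncertain for that reason. The Obp99a call was lost in 3 of 12 fits (adjusted p = 0.126 without group-housed female replicate 0).

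**Figure D2:**
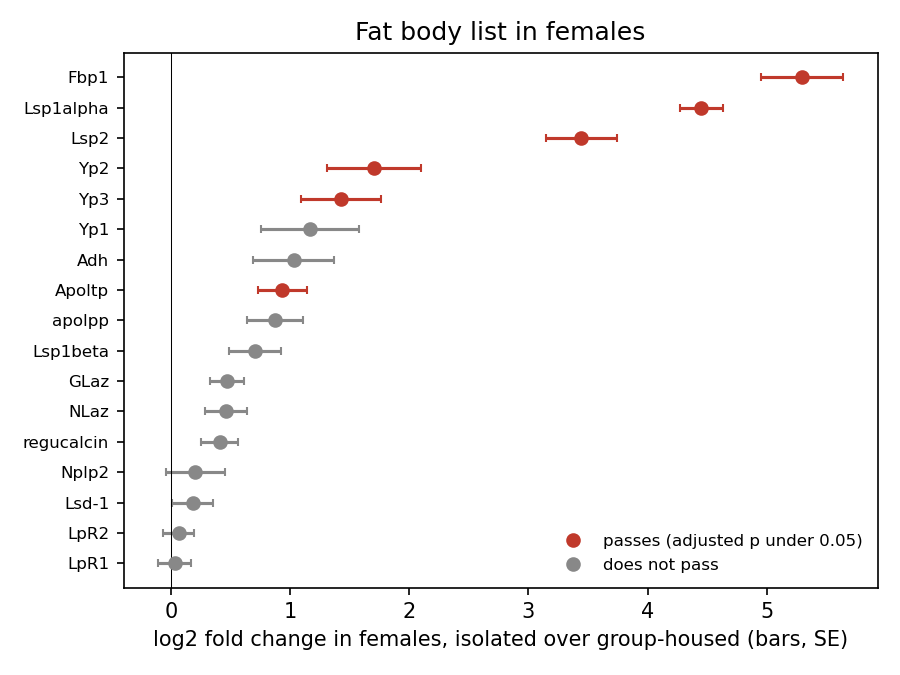
Log2 fold change of the 17 fat body genes in females, isolated over group-housed (horizontal axis), with SE as bars; red points pass the test and grey points do not. Fbp1, Lsp1alpha and Lsp2 lie between 3.44 and 5.30, and LpR1 at 0.03.

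Cytochrome P450 genes, many of which act in detoxification, passed as a list in females. Of 76 cytochrome P450 genes, 22 were higher and 1 lower (25 and 2 adjusted over the list alone; camera adjusted p = 8.46e-09, adjusted p = 0.0397 with an estimated correlation). Cyp4s3, which overlaps a gene on the other strand, Cyp309a1, Cyp309a2 and Cyp9b2 rose by 2.58 (SE 0.19), 1.78 (SE 0.22), 1.57 (SE 0.17) and 1.13 (SE 0.13). In the carbohydrate list 6 of 35 members were higher (7 adjusted over the list alone; camera adjusted p = 9.39e-08, adjusted p = 0.22 with an estimated correlation). They include the alpha-amylase copies Amy-p and Amy-d at 2.69 (SE 0.33) and 1.94 (SE 0.24), and tobi, an alpha-glucosidase gene under insulin control that overlaps a gene on the other strand, at 2.08 (SE 0.20). In the fatty acid and triglyceride list 6 of 25 were higher (10 adjusted over the list alone; camera adjusted p = 1.25e-08, adjusted p = 0.147 with an estimated correlation). Among them the lipase gene bmm rose from 80 ± 2.31 to 143 ± 15.6 CPM (SD, n = 3). Glutathione and UDP transferases had 6 of 50 members higher (8 adjusted over the list alone; camera adjusted p = 0.000578, adjusted p = 0.428 with an estimated correlation).

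Immune and other lists gave smaller counts at the main threshold in females, though lists differ in size. Some lists share members. The 2 FOXO targets that passed, bmm and tobi, are also in the fatty acid and carbohydrate lists. The sex-biased list shares Yp2 and Yp3 with the fat body list, and Obp99a and Obp99b with the odorant binding list. Peptidoglycan recognition and immune signalling genes had 4 of 24 higher, among them Tep2 at 1.03 (SE 0.16) and PGRP-SB1 at 0.64 (SE 0.14) (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00177, adjusted p = 0.428 with an estimated correlation). In the hemocyte and matrix list, eater and LanB2 were higher of 18 tested (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000711, adjusted p = 0.439 with an estimated correlation). Odorant binding proteins had 4 of 31 higher (6 adjusted over the list alone; camera adjusted p = 0.0332, adjusted p = 0.73 with an estimated correlation), and FOXO targets 2 of 14 (2 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.439 with an estimated correlation). None of the 85 cytosolic ribosomal protein genes passed in edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone, and 5 had an unadjusted p under 0.05; the median was -0.13 (camera adjusted p = 0.0301, downward; adjusted p = 0.974 with an estimated correlation). Antimicrobial effectors had 3 of 34 higher, Dso1, Dso2 and BomBc1 (6 adjusted over the list alone; camera adjusted p = 0.595). Calls were lost with 1 library left out for PGRP-SB1 (3 of 12 fits, adjusted p = 0.0963 without isolated female replicate 1), eater (7, 0.188 without isolated female replicate 1), LanB2 (2, 0.099 without isolated female replicate 1) and BomBc1 (2, 0.101 without group-housed female replicate 0).

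In males few genes passed the test of isolation. CG10621 rose from 94.2 ± 1.45 to 182 ± 9.97 CPM (SD, n = 3), a log2 fold change of 0.95 (SE 0.13, adjusted p = 0.00729), and the P450 gene Cyp6a8 from 65.5 ± 8.30 to 118 ± 23.5 CPM (SD, n = 3), at 0.85 (SE 0.15, adjusted p = 0.0329). Both also rose in females. CG34324 fell from 30.6 ± 18.1 to 0.228 ± 0.166 CPM and S-Lap2 from 15.6 ± 19.9 to 0.398 ± 0.182 CPM (SD, n = 3). The others that fell, CG14125, Muc68D, loopin-1 and CG31948, were also close to 0 in isolated males; S-Lap2 and loopin-1 encode sperm proteins. A list of male accessory gland and testis genes took 203, 10.3 and 26.5 CPM in the group-housed male libraries and at most 5.65 CPM in the isolated ones. In all 8 genes passed, and 272 had an unadjusted p under 0.05 where chance alone gives 511.9. Small p-values were thus rarer here than a calibrated test of independent genes would give. The few calls therefore do not show that few genes changed. With the male libraries alone 14 genes passed, with DESeq2 26 and with limma-voom 20. Taken separately in each batch, the changes of all tested genes correlated by r = 0.185 across genes, and 48.3% had the same sign. No gene passed in edgeR in batch 2 alone, where 178 had an unadjusted p under 0.05. The count was 1 without group-housed male replicate 0 or without isolated male replicate 0, 20 without group-housed female replicate 1 or 2, 19 without group-housed male replicate 1, and 15 without isolated female replicate 2 or isolated male replicate 1. CG10621 lost its call in 2 of 12 fits with 1 library left out, group-housed or isolated male replicate 0 (highest adjusted p = 0.113, without the latter). Cyp6a8 lost its call without any 1 of the group-housed male libraries or without isolated male replicate 0 or 2, 5 of 12 fits (highest adjusted p = 0.468, without group-housed male replicate 0).

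In males 7 lists passed with the preset correlation and none with the estimated one. Peptidoglycan recognition and immune signalling genes had a median log2 fold change of 0.20 (0 of 24 passing, 3 higher adjusted over the list alone; camera adjusted p = 4.34e-09, adjusted p = 0.151 with an estimated correlation). Antimicrobial effectors had a median of 0.32 (0 of 34 passing, 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.64e-06, adjusted p = 0.299 with an estimated correlation). Odorant binding proteins and olfactory receptors had medians of 0.24 and 0.43 (camera adjusted p = 2.38e-06 and 1.54e-05; adjusted p = 0.248 and 0.268 with an estimated correlation). Glutathione and UDP transferases and P450 genes had medians of 0.20 and 0.13 (camera adjusted p = 3.41e-07 and 0.000145; adjusted p = 0.201 for each with an estimated correlation), and heat shock and chaperone genes -0.15 (camera adjusted p = 0.000898; adjusted p = 0.151 with an estimated correlation). At an unadjusted p under 0.05 stood 5 of the 24 immune signalling genes and 11 of the 34 antimicrobial effectors; DESeq2 called 2 and 3 of them and limma-voom 0 and 1. The number of lists was 11 without isolated male replicate 0, 12 without group-housed male replicate 2, 13 without isolated male replicate 1 and 15 without isolated male replicate 2.

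The difference between the sexes in their response was tested directly. It passed for 45 genes, 44 with the greater rise in females. Fbp1 differed by 5.47 (SE 0.54, adjusted p = 0.000371), atk by 3.88 (SE 0.24), Lsp1alpha by 3.74 (SE 0.23), Gr59f by 3.62 (SE 0.37) and fiz by 3.16 (SE 0.45). Obp99b, CG34166, Lsp2 and Gnmt, a glycine methyltransferase gene, differed by 2.93, 2.61, 2.53 and 2.23. CG11211 differed the other way, by -1.34 (SE 0.26, adjusted p = 0.0252). Fat body genes differed as a list (3 of 17 higher, 7 adjusted over the list alone; camera adjusted p = 1.99e-31, adjusted p = 0.000237 with an estimated correlation). Sex-biased head genes differed as well (2 of 18 higher, 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.23e-07, adjusted p = 0.0167 with an estimated correlation). Of 32 lists tested, 9 passed with the preset correlation and 2 with the estimated one. The count of genes was 75 without group-housed female replicate 2 and 10 with isolated females represented by replicate 0 alone, where 9 of 15 named genes other than takeout lost their call, among them fiz, Obp99b, Lsp2, Gnmt and CG11211. Obp99b had adjusted p = 0.0508 without isolated female replicate 0, and CG11211 lost its call in 8 of 12 fits with 1 library left out (0.169 without group-housed female replicate 0).

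**Figure D3:**
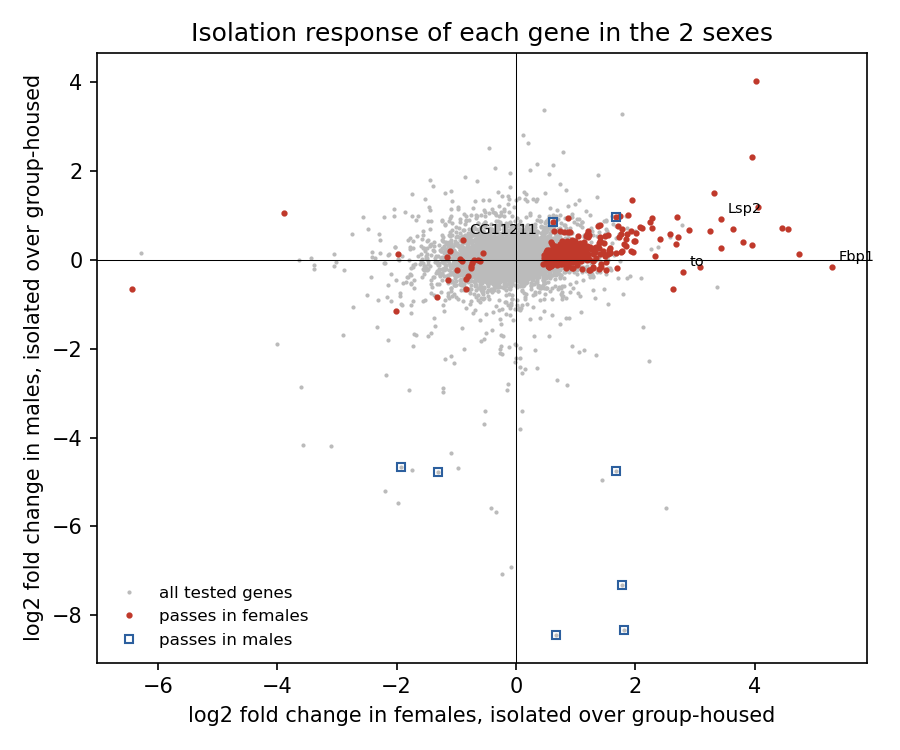
Log2 fold change of each tested gene, isolated over group-housed, in females (horizontal axis) and males (vertical axis); red points pass in females and blue squares in males. The 334 genes higher in females lie to the right, with Fbp1 at 5.30, and takeout lies below 0 in males at -0.28.

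Across 10238 genes, which are not independent replicates, the female and male log2 fold changes were weakly correlated (Pearson r = 0.133, Spearman rho = 0.134; the contrasts share no library). Within batches, from CPM alone, r was 0.203 in batch 1 and 0.108 in batch 2. Of the 334 genes higher in isolated females, 271 (81.1%) had a positive log2 fold change in males, against 49.5% of all tested genes, with a median of 0.15 in males and 0.89 in females. Of the 22 lower genes, 14 were negative in males. Both genes higher in males were also higher in females, where 0.0652 would be shared by chance. The r was 0.02 without isolated female replicate 0 and -0.015 without group-housed female replicate 1. Averaged over the sexes, 213 genes were higher and 12 lower under isolation. Such a call can rest on females alone and does not by itself mean a shared response. takeout passed at 1.26 (SE 0.23) and Fbp1 at 2.56 (SE 0.27), although neither mean level rose in males. In this average Dsk fell by 0.75 (SE 0.12, adjusted p = 0.00211), from 57.8 ± 14.3 to 31.9 ± 2.66 CPM in females and from 60 ± 14.1 to 37.5 ± 0.0942 CPM in males (SD, n = 3). The chaperone gene Hsp83 fell by 0.53 (SE 0.12, adjusted p = 0.0276), and PGRP-SD and AttC, immune genes, rose by 0.91 (SE 0.15) and 0.99 (SE 0.21). With 1 library left out, Hsp83 lost its call in 6 of 12 fits (0.116 without isolated female replicate 2) and AttC in 8 (0.103 without group-housed female replicate 2). The 225 calls were 130 without group-housed male replicate 0, 136 without isolated female replicate 0, 140 without group-housed male replicate 2, 144 without group-housed female replicate 0 and 84 with isolated females represented by replicate 0 alone, where 28 of 52 named genes lost their call, among them Dsk, Hsp83 and AttC.

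The comparison of the sexes matched the labels. Under group housing the dosage compensation RNAs roX1 and roX2 were lower in females by -4.61 (SE 0.22) and -5.07 (SE 0.25), and Obp99a was higher by 4.62 (SE 0.32). takeout was lower in group-housed females than in group-housed males by -2.54 (SE 0.34, adjusted p = 0.000802), and atk by -4.55 (SE 0.19). Under isolation takeout differed by 0.54 (SE 0.32, adjusted p = 0.437). Fbp1, Yp2 and Yp3 were then higher in females by 7.50, 6.01 and 5.92, and Cyp4d21 and sxe2 lower by -3.32 and -2.57. Under group housing 153 genes were higher and 126 lower in females, and under isolation 369 and 65. The share of higher calls under isolation was 85% with TMM and 47.9% with library totals alone. Without group-housed female replicate 0 the first count of 279 was 185, and without group-housed female replicate 2 it was 491. The second, 434, was 288, 207 and 285 without isolated female replicates 0, 1 and 2, 277 and 226 without isolated male replicates 0 and 2, and 62 with isolated females represented by replicate 0 alone.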

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

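The tests of fat body amount, male tissue, male reproductive or gut tissue and splits within batches, and the rule that at least 3 other clock genes follow the clock covariates, were chosen after results were seen, and thinning and the clock covariates were added after seeing the data but before their own results were known. The isolation response differed between the sexes, by a test of the difference itself, for 45 genes. By that test the female response exceeded the male response on the log2 scale by 5.47 for Fbp1, 3.88 for atk, 3.74 for Lsp1alpha, 3.62 for Gr59f, 3.16 for fiz, 3.08 for takeout, 2.93 for Obp99b, 2.61 for CG34166, 2.53 for Lsp2 and 2.23 for Gnmt, and for CG11211 the difference was -1.34. Among 60 of the 200 splits of the libraries within each sex, 7 gave as many genes, the true split included, and the highest other gave 170, so chance in the grouping is not excluded for the number. All 6 others kept the female libraries in their true groups and mixed the males, so these counts follow the structure of the female libraries; with the females mixed the highest was 33. Those splits exchange libraries between the batches, although each group holds 1 library of batch 1; of all 71 splits that keep 1 such library on each side, 10 gave as many, and the highest other gave 218. The true groups with the males exchanged were left out of these, since they turn the difference between the sexes into their average.

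For the rise of many genes in isolated females, the tables argue against lower depth as the whole cause: with every library thinned to 2584050 counts, 313 genes passed, 92.7% of them higher. More fat body tissue, if its profile of transcripts were unchanged, would raise a gene at most by the factor of its abundant transcripts. The 6 listed genes over 1000 CPM in group-housed females, such as Lsp1beta and apolpp, had log2 fold changes of 0.70 to 1.70. Fbp1, Lsp1alpha and Lsp2, 3 of 3, exceeded the highest of these by more than 2 SE. On that assumption tissue amount alone would not give their rises. The assumption was not tested, and the bound comes from the same contrast. The 3 genes, the highest of the list, were picked after their values were seen, so the question is not settled for them. Of the 334 higher genes 18 exceeded that highest value by more than 2 SE. Some others lay above 1.70 but not by that margin, such as Amy-p at 2.69 (SE 0.33) and fit at 2.29 (SE 0.29). The bound depends on where abundance was judged. Lsp1alpha and Lsp2 stood at 74.0 and 480 CPM in group-housed females, but at 1609 and 4638 CPM in isolated females. Judged in isolated females, they would have set a higher bound. The bound therefore does not settle the question for the 18. For the other higher genes it cannot tell a larger amount of this tissue apart from a response. Which of them are expressed in this tissue was not tested. A response to isolation stays open as a hypothesis. The 6 female libraries make 10 splits, too few for a share under 0.05; 1 gave 356 genes, the true one, and the highest other 53, with both batch 1 libraries on one side.

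For takeout, male tissue in the isolated female libraries is argued against by roX1 and roX2, which stood at no more than 6.48% of the isolated male level where takeout would need 157%. With tim and Clk as covariates for the time of freezing, the takeout log2 fold change was 2.56 (SE 0.30). Of all tested genes, 3 followed the covariates after adjustment, and of 10 other clock genes 3 did so at an unadjusted p under 0.05, so this is a weak test, which argues only against a time of day that tim and Clk track as the whole cause. Of the 12 clock genes, 4 had an unadjusted p under 0.05 between isolated and group-housed females. None of the 12 passed in edgeR and 1 passed in DESeq2. Mean tim was 499 ± 262 CPM in group-housed and 308 ± 75.9 CPM in isolated females (SD, n = 3). An equal clock state of the 2 housing groups is thus not shown. A biological response to isolation stays open as a hypothesis, and other technical differences between the housing conditions were not tested.

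For the 6 genes lower in isolated males, the tables argue against testis or gut tissue in group-housed male replicate 0 alone as the whole cause: without that library 6 of 6 kept a log2 fold change below 0 by more than 2 SE, by a criterion that replaced the number of calls after both were seen. Calls ended for 5 of them, with 1 library fewer and adjustment over all genes; S-Lap2 moved from -4.78 (SE 0.72) to -3.35 (SE 0.76, adjusted p = 0.519), while CG34324 moved from -7.32 (SE 0.66) to -7.30 (SE 0.88) and was still called (adjusted p = 0.00341). The genes were called with these libraries included, so the sizes may be overstated, and replicate 0 may add to some of them. Testis tissue in all 3 group-housed male libraries cannot be told apart from a response. The testis list was higher in each of them (lowest 10.3 CPM against at most 5.65 CPM isolated). The gut list was not (lowest 4.0 CPM against at most 5.44 CPM isolated). The 6 genes differed among themselves. S-Lap2 and loopin-1 were highest in replicate 0, at 38.5 and 52.6 CPM, as both lists were. Muc68D and CG34324 stood at 56.0 and 36.1 CPM in replicate 0 and at 56.9 and 45.3 CPM in replicate 1, unlike either list. The 10 splits of the male libraries are too few for a share under 0.05; 1 gave 8 genes, and the highest other 0.

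The splits for the other counts were as follows. For the average over the sexes, 1 of 60 splits gave 225 genes, the true one, and the highest other 218, with the female libraries in their true groups. Of the 71 splits within batches 1 gave as many, with the same highest other. Within batches every split with the females mixed gave 0, and the 10 others with true female groups gave 40 to 218. The share therefore rests on the female grouping, which has only 6 splits within batches, too few for a share under 0.05. Chance is thus not excluded for the female or the male grouping. For the sexes under group housing and under isolation, 10 splits each are too few for a share under 0.05; 1 gave the real 279 and 434, and the highest others 178, with both batch 1 libraries on one side, and 0.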

How the results depend on the processing

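The thinning, the clock covariates, the removal of a pair of libraries and the use of isolated female replicate 0 alone for isolated females were chosen after seeing the data. takeout in females kept its direction and call under every alternative run, at 2.29 to 3.31, with adjusted p of at most 0.0301; in males no alternative made it pass (-0.46 to 0.04). Its difference between the sexes was 2.72 to 3.48 with single libraries left out and lost its call without group-housed female replicate 2, and was 2.56, not passing, with isolated female replicate 0 alone, where calls were 91 in females, 10 for the difference between the sexes, 84 for the average and 62 between the sexes under isolation. No named gene that passed changed sign while either value passed. The causes of the changes below were not tested.

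Calls in females were 168 with library totals alone, 201 against a minimum fold of 1.2, 84 in batch 2 alone and 535 with DESeq2, which shared 355 of the 356, and 158 to 464 with single libraries left out. Calls in males were 254 without a filter, 4 with the strict filter, 5 without batch, 0 in batch 2 alone, 14 in males alone, 26 with DESeq2, 20 with limma-voom, 2 when thinned, 2 without group-housed male replicate 0 and group-housed female replicate 1, which carry gut, testis or eggshell transcripts, and 1 to 20 with single libraries left out. Responses differing between the sexes were 15 with library totals, 168 without a filter, 28 without batch, 12 in batch 2, 141 with DESeq2, 72 with limma-voom, and 30 to 75 with single libraries left out. For the average they were 113 with library totals, 428 without a filter, 89 against a fold of 1.2, 59 in batch 2, 353 with DESeq2, and 130 to 267 with single libraries left out. Between the sexes in groups they were 1019 without a filter, 180 against a fold of 1.2, 112 in batch 2, 442 with DESeq2, 423 with limma-voom, 142 without the pair of libraries, and 185 to 491 with single libraries left out. Under isolation they were 732, 230, 124 and 693 under the first 4 of these, 277 without batch, and 207 to 643 with single libraries left out. Lists that passed fell from 11 to 3 in females, from 7 to 0 in males, from 9 to 2 for the difference and from 15 to 3 for the average with estimated correlation; in males they were 12 with the strict filter and 8 to 15 with single libraries left out. The correlation between the sexes was -0.015 to 0.156 with single libraries left out.

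With library totals alone the median of all genes shifted by -0.21 in females, and with upper-quartile scaling by -0.11. As a block in place of batch, the replicate number moved only the count of responses differing between the sexes by over 1.5 times, to 69, and females had 395 calls; deviations from group means of same-numbered libraries correlated by 0.229 to 0.505 in batch 1 and -0.184 to 0.396 in batch 2, so the numbers were not taken as pairs; within batch 2, differences between replicates 1 and 2 correlated by -0.186 to 0.287 between groups. The 2584050 counts of the shallowest library limit genes of low level; at that depth 9079 features could be tested.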

Other observations

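The overlap with the sex difference was looked at after the results were seen, and its test was written before its value was known. Of the 334 genes higher in isolated females, 49 were also higher in group-housed males than in group-housed females, against 4.11 for independent lists. Among them were takeout, atk, meep, Gr59f, fiz, Obp99b and Gnmt. A further 16 were higher in group-housed females than in group-housed males. No number for independent lists was computed for the 16. The 2 sex lists were of similar size, 126 genes higher in males and 153 in females. The 16 are thus not shown to be few. The isolation and the sex comparison both use the group-housed females. Across genes r was 0.212 and the covariance 0.077, where 20 simulations without any effect gave a mean r of 0.465 and a covariance of 0.066, at most 0.082. Between fold changes from different batches, which share no library, r was 0.127 and 0.103. A shift of isolated females toward the male level may exist for these genes. Across all genes in the full fit it cannot be told apart from the shared libraries, since the covariance lies within the simulated range. The correlations between batches cannot come from shared libraries, but they are small and their spread is not known. The test also required a covariance above every simulated one, so it stays undecided. No simulation gave an overlap above 0, but simulations leave out the real effects.

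Transcripts of the female germline and eggshell list stood at 278 CPM in group-housed female replicate 1, at 74.7 and 27.1 CPM in isolated female replicates 2 and 1, and at no more than 12.4 CPM in the other libraries. Gut digestive enzyme transcripts stood at 146 CPM in group-housed male replicate 0 and at no more than 18.7 CPM elsewhere. The clock gene tim ranged from 220 to 739 CPM among the 3 group-housed female libraries, and from 247 to 393 CPM among the isolated ones.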
